A study of Mus musculus with 12 samples.

How the data were processed

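RNA was measured in mouse (C57BL6) cortical cultures prepared from embryos of embryonic day 16.5 to 17.5. Cultures received a lentivirus carrying miR-29 or an empty lentivirus at a total multiplicity of infection of 2, and were later exposed to oxygen-glucose deprivation (OGD) for 3 h with 4 h of recovery, or to a sham change of buffer in normal oxygen. OGD removes oxygen and glucose from cultured cells as a model of ischemia. Total RNA was treated with DNase, depleted of ribosomal RNA and made into Illumina TruSeq libraries, per the labels' protocols. The design text states that replicates were cultures dissected on distinct days, so same-numbered libraries share a day. There were 4 groups of 3 libraries: sham-empty, sham-miR-29, OGD-empty and OGD-miR-29.

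The authors deposited a table of read counts per gene symbol for the 12 libraries, without normalization. STAR 2.5.0a, featureCounts 1.4.3-p1, edgeR and genome build mm10 are named in the submitters' processing notes, without a role or order. The annotation, the strand setting, the counting region and the gene filter were not given in the sources used here. The authors also deposited 2 comparison tables, OGD-empty against sham-empty and OGD-miR-29 against sham-empty. Per the file headers these hold a log2 fold change, an average log2 CPM, a likelihood ratio score, a p-value and a false discovery rate for each gene. Of the per-sample columns, 0 were left unmapped.

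One column of the deposited count table did not hold read counts. The column labelled sham-empty replicate 3 summed to 22859, against 1337564 to 6616920 in the other 11 libraries, and its Spearman correlation with these across genes was 0.0438 to 0.0978. Among the 11326 gene symbols found in GENCODE M21 (GRCm38), 92.6% of its values were equal to the number of annotated genes on the same strand within the gene and 10 kb downstream of it. The column was therefore left out of every main result, a decision made after its values had been seen. The sham-empty group had n = 2 as a consequence, where the design had assumed 12 libraries.

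The values also showed that a read could be counted for more than 1 gene. The tRNA gene mt-Tf, 68 nt long, held nearly the same count in each library as the neighbouring mt-Rnr1, 955 nt long (110844 and 110849 in sham-empty replicate 1). Of the matched genes, 87.7% had another annotated gene within the gene or 10 kb downstream on either strand. Counts of such genes can hold reads of their neighbours, so these genes are uncertain. For genes where a neighbour held over 0.5 of the gene's own count, a neighbour is mostly named in the results. Neighbours not named there were Gm25788 for Pabpc4, Hnrnpa3 for Nfe2l2, Prrc2a for Aif1, Apoa2 for Fcer1g, Atp5k for Pde6b, Snord14c for Hspa8, Wdr95 for Hsph1 and a RIKEN clone for Sqstm1. In the table, 588 symbols were matched through an older symbol, 231 were not matched and 19 had been turned into dates. Reads shared between near-identical copies cannot be assigned from the table.

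Depth was low. Totals were 1337564 and 2389020 in sham-empty replicates 1 and 2, 2989703, 2586242 and 3849290 in sham-miR-29 replicates 1 to 3, 5765127, 1400957 and 1465641 in OGD-empty, and 6616920, 2518938 and 1901594 in OGD-miR-29. The 37 rows of the mitochondrial genome held 57.6% to 84.1% of the summed counts of each library. A read could be counted in several of these rows, so this is not a share of reads. The totals above are likewise sums over rows that can count a read more than once. Outside the mitochondrial rows the sums were 231500 to 1362484. The median count per gene was 9 to 59. Floors and counting intervals cover counting error only.

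Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; robust fit, TMM scaling, filterByExpr) in 1 fit of the 11 libraries with 4 group means and no replicate block. It kept 12119 of 12145 genes. Adjusted p is the Benjamini-Hochberg value over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with a standard error computed as the fold change divided by the square root of F. CPM values are counts scaled to library size with TMM, given as mean ± SD. There were 7 contrasts: OGD against sham under each virus, miR-29 against empty virus in sham and in OGD, the mean of these virus effects, the interaction, and OGD-miR-29 against sham-empty.

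Of 27 gene lists fixed before the data were examined, 25 had at least 3 members in the test and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Each list was tested again with an estimated correlation, and 0 of the list calls held with it in any contrast. Rows of the mitochondrial genome can hold the same reads, so the 13 mitochondrially encoded genes are not separate measurements. The preset correlation can be too low for that list, and its adjusted p can overstate the evidence in every contrast. Of the inflammatory cytokine and NF-kB list 2 of 24 members were in the table, and of the endothelial and mural cell list 0 of 15, so that neither was tested. The lists tested are immediate early genes, delayed activity-regulated genes, HIF-regulated hypoxia genes, glycolysis, the integrated stress response, endoplasmic reticulum chaperones, heat shock genes, NRF2-regulated antioxidant genes, p53-regulated genes, BH3-only apoptosis genes, interferon-stimulated genes, cholesterol synthesis, nuclear and mitochondrially encoded respiratory chain genes, ionotropic glutamate receptors, glutamate transport and metabolism, matrix and other genes reported as miR-29 targets, and markers of neurons, interneurons, astrocytes, microglia, the oligodendrocyte lineage, fibroblasts and meninges, and proliferation.

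Genes were named by a rule fixed before the data were examined. It took, per contrast, up to 8 called genes with the largest rise and 8 with the largest fall that had a mean of at least 1 CPM and the same sign in every same-numbered pair (predicted genes, clones, pseudogenes and small RNAs left out by their symbols, which kept some small RNAs such as the Y RNAs), up to 4 members of each list by adjusted p, and Slc1a2, Slc1a3 and Vegfa everywhere. With sham-empty replicate 3 left out, contrasts against sham-empty had 2 such pairs. The text names a part of these.

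Matches to the miR-29 seed (TGGTGCT, with TGGTGCTA as the longer form) were searched in the longest annotated 3' UTR of each gene. The difference in mean log2 fold change between genes with and without a match was estimated in a linear model with UTR length and GC content, and ranked among all 7-mers found in at least 100 UTRs. UTRs came from coding transcripts alone, so the alternative of coding transcripts only is the main setting. Gene positions and lengths are from GENCODE M21 on GRCm38, the assembly also called mm10.

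The replicate numbers pair the libraries because the design text ties them to dissection days. In the data, deviations from the group means correlated little across genes between same-numbered libraries (median r = 0.00666 over 15 pairs, from -0.0898 to 0.232). Replicates of a group differed by more than sampling noise, with chi-square per gene of 1.59 to 34.6, and none were counted as a single library.

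The alternatives tried were DESeq2 size factors, no filter and a stricter filter on low counts (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a replicate block, and leaving out each library and each replicate number. For the seed these were other lengths of the match and the shortest UTR. Added after seeing the data were removal of a per-library trend on gene length (loess, span 0.5, on log2 CPM with a prior count of 2), without and with the replicate block, the uncounted column entered as counts, mitochondrial rows left out, and only genes alone in their region.

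The fits were tested on simulated data with 200 changed genes per comparison, 100 at 2-fold and 100 at 4-fold. For OGD in empty-virus cultures 14 of the 2-fold and 78 of the 4-fold changes were recovered among 11899 genes. For OGD in miR-29-virus cultures these were 34 and 90 of 12046 genes, for miR-29 in sham 10 and 73 of 11949, and for miR-29 in OGD 25 and 90 of 11988. For the averaged effect they were 55 and 90 of 11857, for the interaction 3 and 37 of 11913, and for OGD-miR-29 against sham-empty 9 and 72 of 11874. False calls numbered 3 to 16. A length trend planted in the OGD-empty libraries gave a Spearman correlation of 0.608 before and 0.0698 after its removal. A shift of -0.3 planted in genes with a seed match ranked at percentile 0.0128 of 15628 words, and one of -0.1 at percentile 3.19, among 10073 genes. Computations outside R used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1).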

Results

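Cortical cultures carrying an empty or a miR-29 lentivirus were compared after sham treatment or oxygen-glucose deprivation (OGD), with n = 2 libraries for sham-empty and n = 3 for each of sham-miR-29, OGD-empty and OGD-miR-29. The questions addressed were which genes respond to OGD under either virus, and which differ between the viruses. The first principal component held 46.2% of the variance.

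In empty-virus cultures, OGD was accompanied by lower nuclear-encoded respiratory chain genes and higher glutamate receptor genes. Of 29 measured oxidative phosphorylation genes (30 listed), 13 fell and 0 rose, with 23 lower when adjusted over the list alone (median log2 fold change -0.83, camera adjusted p = 4.75e-13; adjusted p = 0.454 with an estimated correlation). Examples were Cox6c (-1.32 ± 0.24, adjusted p = 0.00494, with reads possibly shared with Vps13b), Ndufb5 (-1.28 ± 0.26) and Ndufa4 (-1.15 ± 0.22), subunits of respiratory complexes. Of 14 ionotropic glutamate receptor genes (15 listed), 1 rose, the NMDA receptor subunit Grin2b (1.52 ± 0.37, adjusted p = 0.0331), with 6 higher when adjusted over the list alone (median 1.11, camera adjusted p = 0.000388; adjusted p = 0.654 with an estimated correlation). That list call ended with the per-library gene-length trend removed and the replicate block added (median 0.25, adjusted p = 0.592), and among genes alone in their region (0.86, 0.304), where the respiratory chain call held. In total 617 of 12119 genes were called, 179 higher and 438 lower, and 2876 had an unadjusted p under 0.05, where chance gives about 606. DESeq2 called 717 (331 higher, 386 lower), limma-voom 477 (75 higher, 402 lower), and edgeR with the replicate block 1369 (689 higher, 680 lower). Removal of the length trend made it 606 (193 higher, 413 lower), and without the block 379 (95 higher, 284 lower). A fit of the compared groups alone called 201 (9 higher, 192 lower). Without OGD-empty replicate 1 it was 984 (585 higher, 399 lower), so the balance of rises and falls was not stable.

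In OGD-empty cultures the called immediate early and delayed activity-regulated genes were lower, and called members of the stress response and antioxidant lists went both ways. The integrated stress response (1 higher, 2 lower of 20; median -0.16, adjusted p = 0.832) and antioxidant genes (1 higher, 1 lower of 17, with 5 and 2 when adjusted over the list alone; 0.46, 0.578) were not called as lists. The stress transcription factors Atf3 (-1.40 ± 0.31, adjusted p = 0.0164) and Atf4 (-0.76 ± 0.22, adjusted p = 0.0491) fell, the latter sharing counts with Rps19bp1 and losing its call in 15 of 19 alternatives, among them DESeq2 size factors (0.0517), limma-voom (0.0515) and the omission of any 1 library of the groups compared (0.0526 to 0.369). Slc7a11, the cystine-glutamate exchanger listed under the stress response, antioxidant and glutamate lists, rose (1.78 ± 0.36, adjusted p = 0.0092). Slc7a11 was no longer called with the length trend removed and the replicate block added (0.58 ± 0.42, adjusted p = 0.479). Of 20 immediate early genes (24 listed), 2 fell, Btg2 (-1.40 ± 0.35) and Fos (-1.11 ± 0.30), with 3 lower when adjusted over the list alone. The list's camera adjusted p was 0.0379 (0.0514 with the replicate block, 0.706 with the length trend also removed, 0.304 among genes alone in their region; adjusted p = 0.72 with an estimated correlation), and it was not called without sham-empty replicate 2 (0.467), OGD-empty replicate 1 (0.0524) or OGD-empty replicate 2 (0.22). Rgs2, Mif, Txn1, Npy and Bax fell by 1.38, 1.28, 1.27, 1.17 and 0.93 on the log2 scale, Bax sharing counts with Ftl1 and Gys1. The mitochondrially encoded list was lower (median -0.28, camera adjusted p = 0.0238; adjusted p = 0.72 with an estimated correlation), with 0 of 13 members called, and its adjusted p was 0.104 with the replicate block, 0.959 with the length trend also removed, 0.135 without sham-empty replicate 1 and 0.594 without OGD-empty replicate 2.

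Among the largest falls that met the naming rule in OGD-empty cultures were the Y RNA Rny3 (-2.29 ± 0.42), Rpl10 (-2.27 ± 0.43), Padi2 (-2.18 ± 0.52), Hist1h4a (-2.13 ± 0.40), Snhg1 (-1.98 ± 0.32), Dancr (-1.94 ± 0.46) and Pdia4 (-1.91 ± 0.29). Each of these shares its counting region with a neighbour of at least 0.5 of its count (Rny1 for Rny3 and Pdia4, Snora70 for Rpl10, Sdhb for Padi2, Hist1h4b for Hist1h4a, Snord22 for Snhg1, Snora26 for Dancr), so which gene changed is uncertain. The largest rises by this rule included Thsd7b (2.67 ± 0.64) and Csgalnact1 (2.66 ± 0.65). Nfkb1 had 0 counts over the sham-empty libraries, 45 over OGD-empty and 39 over sham-miR-29. Against a floor of 3 counts over the sham-empty group, OGD-empty was 6.48-fold and sham-miR-29 5.14-fold higher. These folds use totals that include the mitochondrial rows and are not firm lower bounds. The low sham-empty value thus did not set OGD apart from sham in general. Hdx, Nfe2l2 and Ror1 were also called higher, but with 1 to 3 counts over the sham-empty libraries no fold is given. Slc4a4 (2.10 ± 0.53), Mki67 (2.10 ± 0.60, shared with Ptpre) and Bace1 (1.05 ± 0.27, shared with Rnf214) rose, while Slc25a18 (-0.94 ± 0.24, shared with Atp6v1e1) and Kif23 (-1.29 ± 0.27, shared with Rplp1) fell.

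The glutamate transporter Slc1a2 was 0.90 ± 0.27 higher in OGD-empty cultures without passing the threshold (adjusted p = 0.0591), and was called with the replicate block (1.02 ± 0.27, adjusted p = 0.0232) and without OGD-empty replicate 2 (0.0385). Pkm (-0.78 ± 0.23, adjusted p = 0.0521) was likewise called with the block (-0.88, adjusted p = 0.0236). The metallothionein Mt2 (0.81 ± 0.27, adjusted p = 0.0827; 0.0347 with the block, 0.0253 without OGD-empty replicate 2) and Mt1 (0.78 ± 0.28, adjusted p = 0.103; 0.0499 without OGD-empty replicate 2), the latter chosen after its values were seen, were not called. Both were called with the length trend removed and the block added (Mt2 1.28 ± 0.25, adjusted p = 0.00134; Mt1 1.19 ± 0.27, 0.00588). Slc1a3 (0.32 ± 0.27), Vegfa (0.82 ± 0.41) and Aldoa (-0.65 ± 0.20) were not called. The count of 617 became 12 without sham-empty replicate 1, 76 without sham-empty replicate 2, 984 without OGD-empty replicate 1 and 367 without OGD-empty replicate 3. Of the 33 called genes named here, 0 and 4 stayed called without sham-empty replicates 1 and 2, and 20 with the length trend removed and the block added. With that correction the calls lost were Ror1, Slc7a11, Atf4 (-0.45 ± 0.22), Thsd7b (1.35 ± 0.58), Csgalnact1 (1.56 ± 0.51), Txn1 (-1.05 ± 0.33), Btg2 (-1.08 ± 0.39), Fos (-0.79 ± 0.29), Mif (-0.83 ± 0.37), Grin2b (0.46 ± 0.23), Slc4a4 (1.21 ± 0.39), Npy (-0.95 ± 0.32) and Bax (-0.67 ± 0.25). A fit of the compared groups alone kept 12 of the 28 named calls that it tested. Limma-voom kept 26 of 33, and DESeq2 21 of the 21 to which it gave an adjusted p.

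In miR-29-virus cultures, OGD raised the metal-binding metallothioneins Mt1 (1.83 ± 0.23) and Mt2 (1.79 ± 0.23), both with an adjusted p of 0.000743 and higher in 3 of 3 pairs. Mt1 lies within 10 kb downstream of Mt2 on the same strand, so that Mt2 can hold reads of Mt1. Mean Mt1 rose from 20.03 ± 5.07 CPM in sham-miR-29 to 71.2 ± 18.8 CPM in OGD-miR-29. These 2 were the only called genes of 12119 by edgeR, DESeq2 and limma-voom, with 1111 genes at an unadjusted p under 0.05. The replicate block gave 5, and leaving out replicate 1 in all groups gave 0 (Mt1 adjusted p = 0.145).

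**Figure D1:**
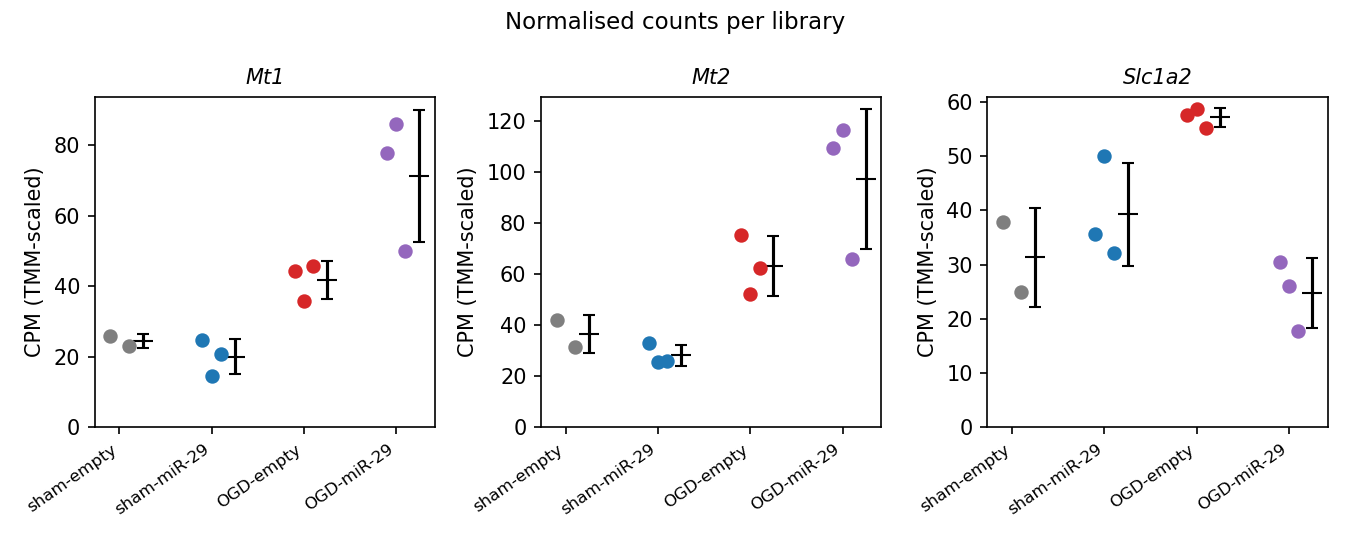
Mt1, Mt2 and Slc1a2 in TMM-scaled CPM (y axes, starting at 0) for each library by group (x axes), with points for libraries and bars for the group mean ± SD. Mt1 lies at 49.999 to 85.9 CPM in OGD-miR-29 and at 14.6 to 24.6 CPM in sham-miR-29.

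List tests in miR-29-virus cultures called 8 of 25 lists, with an adjusted p of 0.106 to 0.566 with an estimated correlation. Higher were antioxidant genes (median 0.27, adjusted p = 5.94e-05), oxidative phosphorylation (0.32, 2.51e-05), glycolysis (0.19, 0.00834) and heat shock genes (0.41, 0.00834). Lower were delayed activity-regulated genes (-0.36, 0.00408), immediate early genes (-0.28, 0.00522), mitochondrially encoded genes (-0.47, 0.00275) and glutamate receptors (-0.40, 0.00834). Of their members, Mt1 and Mt2, which the antioxidant list holds, were called over all genes. Members of the 25 tested lists, called as lists or not, that were not called as genes included Hspa8 (0.88 ± 0.19), Hmox1 (0.97 ± 0.25), Ddit3 (0.86 ± 0.20), Fosl2 (-1.11 ± 0.22), Homer1 (-0.88 ± 0.19), Creld2 (1.35 ± 0.39), Herpud1 (0.71 ± 0.23) and Tpi1 (0.72 ± 0.24, shared with Spsb2). Hspa8 (0.81 ± 0.17, adjusted p = 0.0317) and Fosl2 (-1.10 ± 0.20, 0.0049) were called with the length trend removed and the block added, the latter also among genes alone in their region (0.028). Slc1a2 (-0.63 ± 0.23, adjusted p = 0.479), Slc1a3 (-0.04 ± 0.22) and Vegfa (0.51 ± 0.29) were not called. Heat shock genes were not called without OGD-miR-29 replicate 3 (0.0723), nor glycolysis without sham-miR-29 replicate 2 (0.0838) or OGD-miR-29 replicate 3 (0.0539). The same held for glutamate receptors without sham-miR-29 replicate 2 (0.098) or with the length trend removed and the block added (0.124), mitochondrially encoded genes without OGD-miR-29 replicate 3 (0.16), delayed genes without sham-miR-29 replicate 3 (0.0547), and immediate early genes without sham-miR-29 replicate 3 (0.108) or OGD-miR-29 replicate 1 (0.0507). Among genes alone in their region antioxidant genes (0.17, 0.689), oxidative phosphorylation (0.38, 0.0713), delayed genes (-0.27, 0.689) and glutamate receptors (-0.20, 0.689) were not called. Lists called only in alternatives were endoplasmic reticulum chaperones without OGD-miR-29 replicate 2 (0.0278), and interneuron markers, lower, without OGD-miR-29 replicate 1 (0.0472) or 2 (0.0227) or with the length trend removed and the block added (-0.26, 0.0347).

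In sham cultures, miR-29 virus against empty virus gave 0 called genes by edgeR, DESeq2 and limma-voom, with 405 at an unadjusted p under 0.05 by edgeR. Slc1a2 (0.35 ± 0.27), Slc1a3 (0.23 ± 0.27), Vegfa (0.36 ± 0.43), Fos (0.55 ± 0.29), Fosl2 (0.80 ± 0.26) and the genes reported as miR-29 targets Fbn1 (1.14 ± 0.65) and Tdg (-1.15 ± 0.53) were not called. Immediate early genes were higher as a list (median 0.26, adjusted p = 0.0255), and mitochondrially encoded (-0.33, 0.00777) and oxidative phosphorylation genes (-0.16, 0.0482) lower, each with an adjusted p = 0.749 with an estimated correlation. With the replicate block the first and second had an adjusted p of 0.121, and with the length trend also removed of 0.0934 and 0.192. Immediate early genes were not called without sham-empty replicate 1 (0.473) or sham-miR-29 replicate 3 (0.376), nor mitochondrially encoded genes without these (0.281 and 0.376). Oxidative phosphorylation was not called without sham-empty replicate 1 (0.281), sham-empty replicate 2 (0.24) or sham-miR-29 replicate 2 (0.628), nor with mitochondrial rows left out (-0.15, 0.0803). Among genes alone in their region neither it (0.103) nor the immediate early list (0.0516) was called.

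Under OGD, miR-29-virus cultures had higher respiratory chain and glycolysis genes and lower glutamate receptor genes than empty-virus cultures. Of 29 oxidative phosphorylation genes 27 were higher and 0 lower (median 1.07, camera adjusted p = 2.07e-11; adjusted p = 0.391 with an estimated correlation), among them Sdhb (shared with Atp13a2) and Cox4i1 (1.37 ± 0.21, shared with Gm20388). Of 14 glutamate receptor genes 12 were lower (median -1.58, camera adjusted p = 4e-05; adjusted p = 0.541 with an estimated correlation), including Grin2b (-2.20 ± 0.32), Gria3 (-2.17 ± 0.36), Gria4 (-1.92 ± 0.38) and Gria2 (-1.40 ± 0.24). With the length trend removed and the replicate block added the receptor median was -0.48 and its adjusted p 0.0824, and among genes alone in their region -0.95 and 0.295. Of 23 glycolysis genes (24 listed) 8 were higher and 1 lower (median 0.47, camera adjusted p = 0.0244; adjusted p = 0.541 with an estimated correlation; 0.0519 without OGD-miR-29 replicate 3), with Tpi1 (1.35 ± 0.24, shared with Spsb2), Pkm (1.15 ± 0.21) and Aldoa (0.90 ± 0.18) rising. In total 4501 of 12119 genes were called, 2085 higher and 2416 lower, with 5738 at an unadjusted p under 0.05. Removing the length trend and adding the block gave 3040 called, of which 2240 were among the 4501. DESeq2 called 3462 and limma-voom 4424, and leaving out replicate 1 or 3 in all groups gave 2664 or 2582. Of the 62 called genes named for this comparison, 50 to 57 stayed called without any 1 OGD library. DESeq2 kept 55, and the calls it lost included Bnip3, Mif, Fbn1, Fcer1g and Mki67. Of the 60 that have a length, 40 stayed called with the length trend removed and the block added, those lost being Slc1a2, Slc7a11 and the following. Nav3 (0.41 ± 0.20) and Reln (0.50 ± 0.25), lower before, were then on the higher side. Lower before were also Syt1 (-0.38 ± 0.21), Map2 (-0.11 ± 0.22), Hdac4 (-0.39 ± 0.20), Homer1 (-0.22 ± 0.18), Lamc1 (-0.38 ± 0.26), Adamts17 (-0.04 ± 0.28) and Fbn1 (-0.11 ± 0.31). Higher before were Arc (0.51 ± 0.25), Gadd45g (0.80 ± 0.34), Bbc3 (0.66 ± 0.26), Bnip3 (0.47 ± 0.22), Mif (0.34 ± 0.29), Npy (0.49 ± 0.25), Sox10 (0.82 ± 0.37), Ptgds (0.49 ± 0.28) and Fcer1g (0.63 ± 0.37).

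Slc1a2 was lower in OGD-miR-29 than in OGD-empty cultures (-1.18 ± 0.23, adjusted p = 0.000966, lower in 3 of 3 pairs), with means of 24.8 ± 6.44 and 57.2 ± 1.79 CPM. It lies on chromosome 2 from 102658659 to 102790784, a long gene, and with the length trend removed and the replicate block added its difference was -0.47 ± 0.20 (adjusted p = 0.0695), a smaller fold with a similar error. Slc7a11 (-1.28 ± 0.25, adjusted p = 0.00109) went to 0.08 ± 0.26 (adjusted p = 0.867) under the same correction, its fold having ended. Slc1a3 (-0.13 ± 0.22) and Vegfa (0.05 ± 0.28) were not called. Of 17 glutamate transport and metabolism genes (22 listed) 2 were higher and 5 lower (median -0.13, adjusted p = 0.471).

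The remaining lists were not called under OGD between the viruses, although many members were, and 3 of these lists were called in alternatives. Immediate early genes had 7 higher and 2 lower of 20 (median 0.54, adjusted p = 0.142), with Btg2 (1.23 ± 0.28), Junb (1.01 ± 0.20, shared with Prdx2) and Arc (0.94 ± 0.27) higher. Delayed activity-regulated genes had 2 higher and 2 lower of 14 (16 listed; -0.14, 0.848), with Gadd45g (1.26 ± 0.34) higher and Homer1 (-0.83 ± 0.19) lower. HIF-regulated genes had 3 higher of 20 (27 listed; 0.14, 0.477), 0 of them when adjusted over the list alone, with Mif at 0.76 ± 0.30 and Bnip3 at 0.64 ± 0.22 (shared with Ppp2r2d). The integrated stress response had 4 higher and 4 lower of 20 (23 listed; 0.37, 0.471), Atf3 (1.08 ± 0.26), Atf4 (0.97 ± 0.19) and Ddit3 (0.92 ± 0.20) being higher. Endoplasmic reticulum chaperones had 8 higher of 19 (20 listed, median 0.46, adjusted p = 0.0839). These included Pdia4 (1.61 ± 0.26, shared with Rny1), Pdia6 (1.22 ± 0.23, shared with Atp6v1c2) and Herpud1 (1.14 ± 0.23). Heat shock genes had 6 higher and 1 lower of 13 (18 listed; 0.57, 0.287; 7 and 2 when adjusted over the list alone), Hspa8 at 1.01 ± 0.19 and Hsph1 at -0.86 ± 0.22. Antioxidant genes had 9 higher and 3 lower of 17 (20 listed; 0.54, 0.434), with Sqstm1 at 0.80 ± 0.19. For p53-regulated genes it was 4 and 1 of 15 (20 listed; 0.18, 0.471), with Zmat3 at -1.16 ± 0.28, and for BH3-only genes 2 and 0 of 7 (9 listed; 0.46, 0.506), with Bbc3 at 1.00 ± 0.32 (shared with Sae1). Interferon-stimulated genes had 0 called of 3 (20 listed; -0.19, 0.793), and mitochondrially encoded genes 0 of 13 (-0.51, 0.471). The latter list was called lower with the length trend removed and the block added (-0.86, 0.000365) and without OGD-empty replicate 2 (-0.83, 0.0122). Chaperones were called without OGD-miR-29 replicate 2 (0.52, 0.0484), and immediate early genes without replicate 3 in all groups (0.74, 0.0266). Cholesterol synthesis had 3 higher and 2 lower of 20 (22 listed; 0.10, 0.793), with Fdft1 at 0.76 ± 0.19 (shared with Ctsb) and Stard4 at -1.32 ± 0.32 (shared with Camk4).

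Genes reported as miR-29 targets were measured in 2 lists. Of 15 matrix genes (35 listed) 5 were lower and 0 higher in OGD-miR-29 than in OGD-empty cultures (median -0.15, adjusted p = 0.471), with Adamts17 (-1.23 ± 0.32), Fbn1 (-1.07 ± 0.38) and Lamc1 (-1.04 ± 0.28). Of 37 other targets (45 listed) 17 were lower and 6 higher (18 and 6 when adjusted over the list alone; -0.50, 0.175), with Hdac4 (-1.54 ± 0.28) and Nav3 (-1.25 ± 0.25) lower, neither called with the length trend removed, and Calm3 (1.19 ± 0.22, shared with Ptgir) and Vdac1 (0.86 ± 0.19) higher. Among 10058 genes with an annotated 3' UTR, 1687 held a match to the miR-29 seed TGGTGCT. With UTR length and GC content in the model, genes with a match differed from the rest by 0.00237 on the log2 scale under OGD, which ranked at percentile 82.4 of 15624 words. With the 8-mer alone the difference under OGD was -0.0367 (percentile 54.3). In sham the difference for the 7-mer was -0.00119 (percentile 32.4) and averaged over both 0.00059 (percentile 77.8). Without these covariates, camera placed genes with a match lower under OGD (adjusted p = 0.00462; p = 0.0684 with an estimated correlation). That call ended with the length trend removed (adjusted p = 0.150, or 0.146 with the block), with the shortest UTR (0.436) and among genes alone in their region (0.367). The averaged effect was also called lower by camera (adjusted p = 0.00922; p = 0.0962 with an estimated correlation), which likewise ended with the length trend removed (0.215, or 0.288 with the block).

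Cell type markers went both ways between the viruses under OGD. Of 18 neuron markers 5 were higher and 7 lower (median 0.10, mean -0.22, test direction down, adjusted p = 0.718), with Syt1 (-1.82 ± 0.33), Celf4 (-1.77 ± 0.34) and Map2 (-1.16 ± 0.24) lower and Nefl (1.09 ± 0.22, shared with Nefm) higher. Interneuron markers had 2 higher and 3 lower of 12 (14 listed; -0.04, 0.758), Npy at 0.85 ± 0.27 and Reln at -0.80 ± 0.22, neither called with the length trend removed. Astrocyte markers had 1 higher and 2 lower of 11 (15 listed; -0.13, 0.699), Slc25a18 at 0.86 ± 0.21 and Slc4a4 at -2.01 ± 0.38. Microglia markers had 2 higher of 5 (14 listed; 0.39, 0.314), Aif1 and Fcer1g, both sharing their region, and the oligodendrocyte lineage 2 of 6 (15 listed; 0.29, 0.471), including Sox10 (1.14 ± 0.38, shared with Polr2f). Fibroblast and meningeal markers had 1 higher of 3 (14 listed, median 0.39, adjusted p = 0.471), Ptgds at 0.94 ± 0.32 (shared with Clic3). Proliferation genes had 2 higher and 1 lower of 7 (20 listed, median 0.73, adjusted p = 0.287). They included Kif23 at 1.35 ± 0.23 (shared with Rplp1) and Mki67 at -1.06 ± 0.36 (shared with Ptpre). Mki67 was not called with DESeq2, nor without OGD-empty replicate 1, OGD-miR-29 replicate 1 or OGD-miR-29 replicate 2. Among genes that met the naming rule (called, a mean of at least 1 CPM, the same sign in each pair, predicted genes, clones, pseudogenes and small RNAs left out by symbol), the largest differences included the falls of Alk (-3.03 ± 0.77), Ntng1 (-2.94 ± 0.57), Ghr (-2.91 ± 0.57), Npas3 (-2.88 ± 0.68), B3galt1 (-2.85 ± 0.78), Nkain3 (-2.82 ± 0.64) and Rmst (-2.76 ± 0.64), and the rises of Padi2 (2.36 ± 0.40), Dancr (2.08 ± 0.36) and Pde6b (1.96 ± 0.29), the rises all sharing counts with neighbours. These 7 falls are in the longest of 5 equal groups of genes by length, where 1396 of 2378 genes were called lower (median -0.97). They stayed called with the length trend removed and the replicate block added, unlike Syt1 and Map2. OGD-empty replicate 2 stood apart from replicates 1 and 3 (first principal component 76.3 against 36.5 and 41.2; 57.6% of counts in mitochondrial rows), and without it these 7 falls stayed called at -2.18 to -1.88. Alk was not called without OGD-miR-29 replicate 1 (0.063), 2 (0.0526) or 3 (0.0557), nor B3galt1 without these (0.0761, 0.0711 and 0.0662), nor Npas3 without OGD-miR-29 replicate 3 (0.0529).

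**Figure D2:**
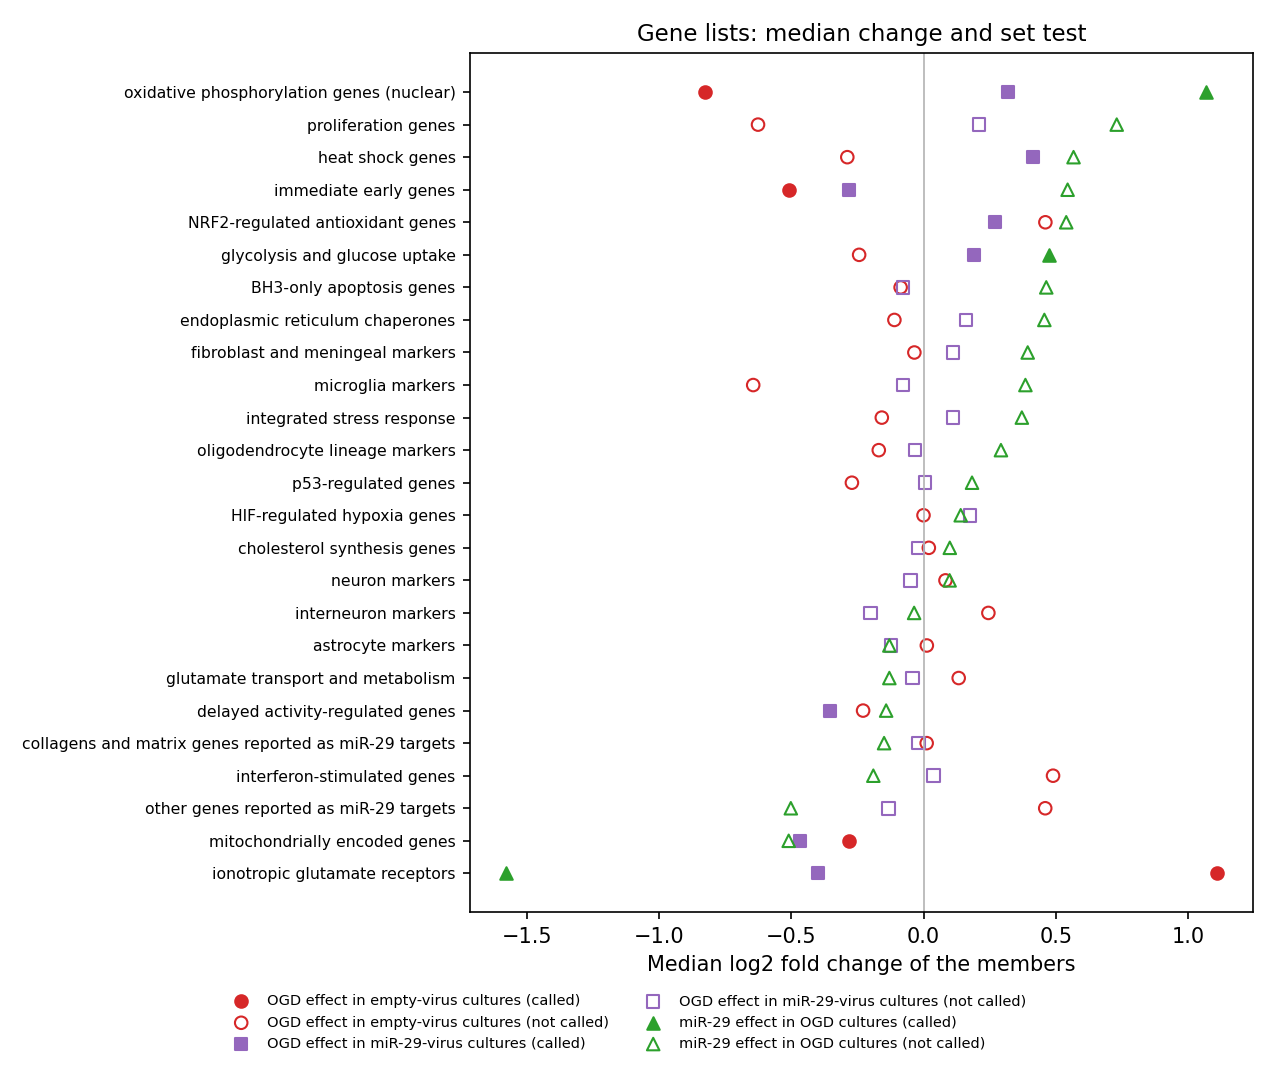
Median log2 fold change of the measured members (x axis) of the 25 tested gene lists (y axis) for OGD under either virus and for miR-29 virus under OGD, with filled symbols where camera's adjusted p is under 0.05. The oxidative phosphorylation medians are -0.83, 0.32 and 1.07, and the glutamate receptor medians 1.11, -0.40 and -1.58.

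Averaged over sham and OGD, the miR-29 effect gave 0 called genes by edgeR and by limma-voom, 708 by DESeq2, and 3062 at an unadjusted p under 0.05 by edgeR. The smallest adjusted p was 0.0505, shared by Grin2b (-1.10 ± 0.23), Gria2 (-0.74 ± 0.18), Cox4i1 (0.72 ± 0.16), Pdia6 (0.78 ± 0.18) and Tubb3 (0.68 ± 0.15), of which Cox4i1 and Tubb3 share counts with Gm20388. Fos (0.69 ± 0.19), Arc (0.74 ± 0.22), Slc1a2 (-0.42 ± 0.18, adjusted p = 0.155), Slc1a3 (0.05 ± 0.17) and Vegfa (0.21 ± 0.26) were not called. Lists called higher were oxidative phosphorylation (median 0.45, adjusted p = 1.42e-07), immediate early genes (0.46, 0.00507), glycolysis (0.28, 0.0071) and endoplasmic reticulum chaperones (0.32, 0.0174), and lower were glutamate receptors (-0.79, 1.74e-05) and mitochondrially encoded genes (-0.42, 0.0424; 0.091 with the block). With the length trend removed and the block added, glutamate receptors (-0.21, 0.0867), immediate early genes (0.24, 0.235) and endoplasmic reticulum chaperones (0.20, 0.131) were not called. Among genes alone in their region oxidative phosphorylation (0.51, 0.0991), immediate early genes (0.35, 0.105) and glutamate receptors (-0.64, 0.0991) were not called. With an estimated correlation the adjusted p of the 6 lists was 0.391 to 0.72. Counts were 885 without sham-miR-29 replicate 2, 868 without OGD-empty replicate 1, 913 without OGD-empty replicate 2 and 436 without OGD-miR-29 replicate 1. The mitochondrially encoded list was not called without sham-empty replicate 1 (0.0887), sham-miR-29 replicate 3 (0.163), OGD-empty replicate 1 (0.523) or 3 (0.0931), or OGD-miR-29 replicate 2 (0.0636) or 3 (0.288).

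The OGD effect differed between the viruses for 1015 genes by the interaction test, 572 with a higher and 443 with a lower OGD effect in miR-29-virus cultures, with 3379 at an unadjusted p under 0.05. DESeq2 called 1044 (482 and 562), limma-voom 836 (555 and 281), and the replicate block gave 1861 (888 and 973). Removal of the length trend gave 678 (449 and 229). Positive interactions included Padi2, Dancr, Rpl10 and Pabpc4, all sharing their region, as well as Ndufb5 (1.68 ± 0.33), Cox6c (1.48 ± 0.32), Ddit3 (1.36 ± 0.32), Pkm (1.21 ± 0.31) and Hspa8 (1.17 ± 0.30). Negative ones included Grin2b (-2.20 ± 0.48), Hdac4 (-1.81 ± 0.44), Nav3 (-1.56 ± 0.39), Bace1 (-1.34 ± 0.34) and Gria2 (-1.30 ± 0.36). Of the 14 called interactions named that have a gene length, 9 stayed called with the length trend removed and the block added. Grin2b (-0.78 ± 0.30, adjusted p = 0.0986), Hdac4 (-0.70 ± 0.33, 0.181), Gria2 (-0.61 ± 0.30, 0.207), Nav3 (0.06 ± 0.33, 0.944) and Slc1a2 did not, nor did Hspa8 without the block (0.87 ± 0.29, 0.0619). Slc1a2 had an interaction of -1.53 ± 0.36 (adjusted p = 0.0158), not called without sham-empty replicate 1 (-1.83, adjusted p = 0.0536) or 2 (-1.24, adjusted p = 0.15), nor with the length trend removed and the block added (-0.88 ± 0.32, adjusted p = 0.0804). The interaction of Mt1 (1.05 ± 0.36, adjusted p = 0.07; 0.0477 without OGD-miR-29 replicate 3), of Slc1a3 (-0.36 ± 0.35) and of Vegfa (-0.31 ± 0.51) was not called. Oxidative phosphorylation (median 1.22, 18 of 29 higher, adjusted p = 4.28e-13; adjusted p = 0.496 with an estimated correlation) and glutamate receptors (median -1.55, 3 of 14 lower, adjusted p = 0.0002; adjusted p = 0.536 with an estimated correlation) were called as lists. The receptor call ended with the length trend removed and the block added (median -0.44, adjusted p = 0.222), and among genes alone in their region (-0.98, 0.466), where the oxidative phosphorylation call held. The count was 64 without sham-empty replicate 1, 93 without sham-empty replicate 2, 647 without sham-miR-29 replicate 1, 308 without sham-miR-29 replicate 2, 634 without OGD-miR-29 replicate 2 and 439 without OGD-miR-29 replicate 3.

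OGD-miR-29 against sham-empty cultures gave 0 called genes by edgeR, DESeq2 and limma-voom, with 841 at an unadjusted p under 0.05 by edgeR. Mt1 (1.55 ± 0.28, adjusted p = 0.212) and Mt2 (1.43 ± 0.28, adjusted p = 0.22) had an adjusted p of 0.000894 and 0.00197 in a fit of the compared groups alone, which called 16 genes, and of 0.0207 without OGD-miR-29 replicate 3, which called 2. Both had an adjusted p of 0.00462 with the length trend removed and the block added. In the authors' table of this comparison Mt1 (1.82) and Mt2 (1.71) passed a false discovery rate of 0.05, but its values were closest to a fit that included the column without read counts (r = 0.993 with it and 0.828 without it), so it is not independent support. Hmox1 (1.20 ± 0.32), Herpud1 (0.79 ± 0.28), Vegfa (0.87 ± 0.41), Slc1a2 (-0.29 ± 0.28), Slc1a3 (0.19 ± 0.27) and Pik3r1 (-0.69 ± 0.25) were not called. Antioxidant genes (median 0.37, adjusted p = 0.000745), glycolysis (0.25, 0.00357) and endoplasmic reticulum chaperones (0.35, 0.0125; 0.0523 without sham-empty replicate 2, 0.067 without OGD-miR-29 replicate 3) were higher as lists. Mitochondrially encoded genes (-0.79, 1.46e-09) and glutamate receptors (-0.51, 0.0139; 0.0577 with the block, 0.199 without sham-empty replicate 1, 0.0604 without OGD-miR-29 replicate 3) were lower. Members of the mitochondrially encoded list can hold the same reads, so its small adjusted p can overstate the evidence. With the length trend removed and the block added, the chaperones (0.0756) and glutamate receptors (0.259) were not called. Among genes alone in their region antioxidant genes (-0.03, 0.997) and glutamate receptors (-0.52, 0.997) were not called. Lists called only in alternatives were delayed activity-regulated genes, lower, without sham-empty replicate 1 (0.0237) or OGD-miR-29 replicate 2 (0.0243) or with the length trend removed and the block added (-0.26, 0.0461), and oxidative phosphorylation, higher, without OGD-miR-29 replicate 1 (0.0352) or 2 (0.0243). With an estimated correlation the adjusted p of these lists was 0.177 to 0.604.

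The authors' table of OGD-empty against sham-empty held 6 genes past a false discovery rate of 0.05, Asap1, Gm10722, Snora15, Snora70, Gm25107 and Rpl10, of which 5 were called here in the same direction. Across genes, which are not independent replicates, its log2 fold changes correlated with those here at r = 0.903, and at r = 0.995 with a fit of the compared groups that had the replicate block and the column without read counts entered as counts. The same form of fit without that column gave r = 0.910. For OGD-miR-29 against sham-empty these were 0.811, 0.993 and 0.828. Both tables thus lay closer to fits with the column, which holds no read counts, and appear to have been computed with it.

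Fold changes followed gene length. Across 11891 genes, which are not independent replicates, Spearman's correlation of fold change with gene length was 0.528 for OGD in empty-virus cultures, -0.321 for OGD in miR-29-virus cultures, 0.0215 for miR-29 in sham and -0.579 for miR-29 under OGD. For OGD in empty-virus cultures the median log2 fold change went from -0.41 in the shortest of 5 equal groups of genes to 0.70 in the longest. For miR-29 under OGD it went from 0.54 to -0.97. By library the correlation was 0.411 to 0.591 in OGD-empty, 0.164 in sham-miR-29 replicate 2 and -0.462 to -0.0891 in the other 7.

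**Figure D3:**
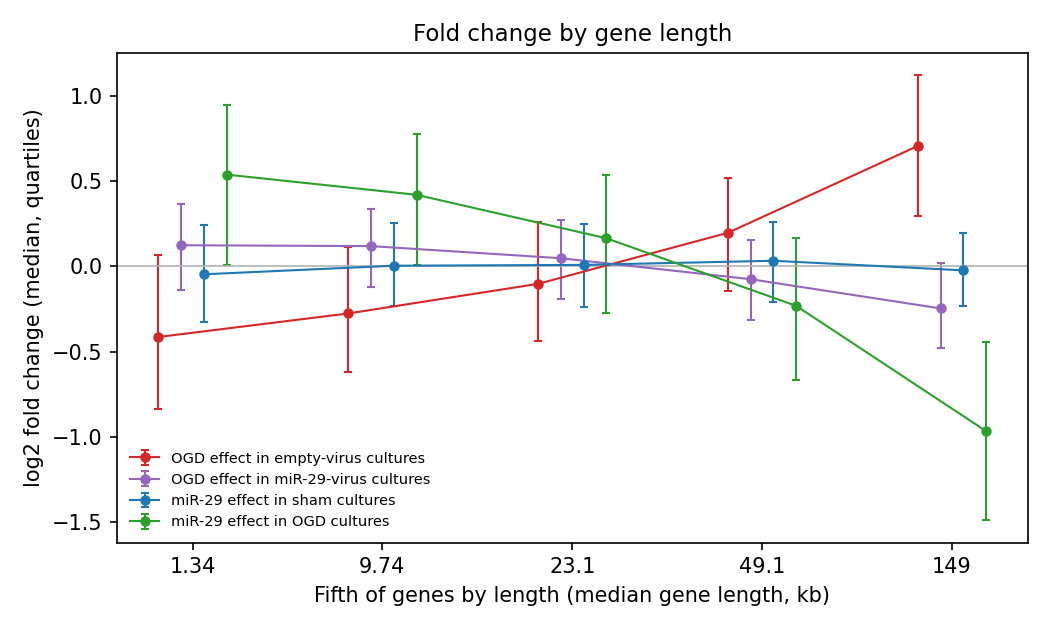
Median log2 fold change with quartiles (y axis) in 5 equal groups of genes by length (x axis, median gene length in kb) for 4 comparisons. OGD in empty-virus cultures rises from -0.41 to 0.70, and miR-29 under OGD falls from 0.54 to -0.97.

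**Figure D4:**
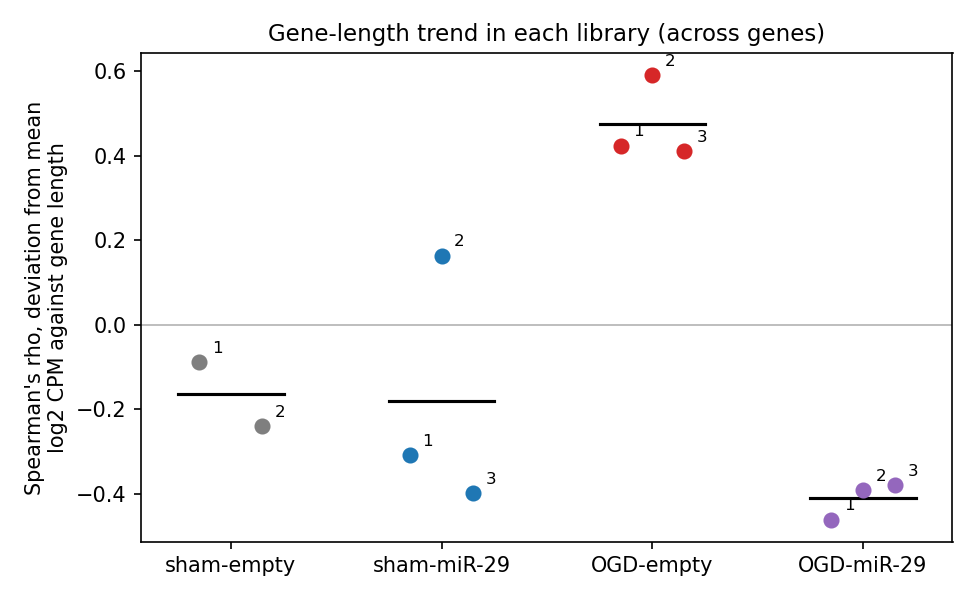
Spearman correlation across genes of each library's deviation from the mean log2 CPM with gene length (y axis), by group (x axis), with points for libraries labelled by replicate number and lines for group means. The OGD-empty libraries lie at 0.411 to 0.591 and the OGD-miR-29 libraries at -0.462 to -0.38.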

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

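The tests of depth outside the mitochondrial rows, of an additive background and of OGD acting alike under either virus, and every value with the gene-length trend removed, were chosen after the results were seen.

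The OGD effect differed between empty-virus and miR-29-virus cultures by the interaction test for 1015 genes. On the log2 scale the interaction was 2.73 for Padi2, 2.53 for Dancr, 2.51 for Rpl10, 2.44 for Pabpc4, 1.68 for Ndufb5, 1.48 for Cox6c, 1.36 for Ddit3, 1.21 for Pkm and 1.17 for Hspa8. It was -2.20 for Grin2b, -1.81 for Hdac4, -1.56 for Nav3, -1.53 for Slc1a2, -1.34 for Bace1 and -1.30 for Gria2. As lists, oxidative phosphorylation genes had a median interaction of 1.22 and ionotropic glutamate receptors of -1.55. The receptor call ended with the length trend removed and the replicate block added (-0.44, camera adjusted p = 0.222). Neither list was called by camera with an estimated correlation (adjusted p = 0.496 and 0.536). Hdx was also called with a lower OGD effect in miR-29-virus cultures, but with 1 count over the sham-empty libraries no fold is given. All of these rest on 2 sham-empty libraries. Of the 15 called genes given with a value, 2 stayed called without sham-empty replicate 1 and 1 without sham-empty replicate 2. Of the 14 that have a gene length, 9 stayed called with the length trend removed and the block added, the others being Grin2b (-0.78), Hdac4 (-0.70), Slc1a2 (-0.88), Gria2 (-0.61) and Nav3 (0.06).

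Long genes were higher and short genes lower in the OGD-empty libraries. Against the shared counting region as the source, the correlation with gene length was 0.635 in genes alone in their region, and against depth it was 0.566 after every library was thinned to equal totals and 0.596 after thinning to equal counts with mitochondrial rows left out. OGD acting alike under either virus is argued against by a correlation of -0.321 in miR-29-virus cultures. The size of this value leans on sham-miR-29 replicate 2, at 0.164 by library. Sham-miR-29 replicates 1 and 3 were at -0.309 and -0.399, near the OGD-miR-29 libraries (-0.462 to -0.38). No OGD-miR-29 library had the positive trend of the OGD-empty libraries (0.411 to 0.591). An additive background along the genome, such as genomic DNA or unspliced RNA, stays open as a candidate explanation: among the longest genes the 744 densest in counts rose less than the 744 sparsest, by a median difference of -0.77 (95% interval -0.837 to -0.684; -0.29 among genes matched for length). An OGD response that depends on the virus also stays open, as untested.

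Genes differing between miR-29 and empty virus under OGD were weighed against the length trend and against repression through the miR-29 seed. With the length trend removed and the replicate block added, 64.9% as many genes were called as with the block alone, a ratio of counts. Of these 3040 genes, 2240 were among the 4501. The trend on length as fitted here thus does not account for all calls. The correction acts on length alone, so an additive background that also depends on count density stays open for the calls that stayed. Of the 60 called genes named that have a length, 40 stayed called with the trend removed and the block added, and Slc1a2, Slc7a11, Syt1, Map2, Hdac4, Nav3, Reln and the glutamate receptor list were among the calls lost. The seed match ranked at percentile 82.4 of all 7-mers under OGD (54.3 for the 8-mer) and 32.4 in sham, where strong repression would place it among the lowest. In simulated values a planted shift of -0.3 ranked at percentile 0.0128. One of -0.1, recovered as -0.0653, ranked at 3.19. In the data the lowest 2.5% of words lay below -0.145 under OGD and below -0.0297 in sham. Under OGD a difference of -0.1 would thus not have ranked among these. The rank cannot decide about a shift of that size under OGD, or about a smaller shift in either. The counts also appear to cover whole gene regions, in which a change of mature transcripts could look smaller. An indirect effect of the virus, or a difference of the OGD-empty libraries from all others, stays open.

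Other splits of the libraries were fitted for each count of called genes. For OGD in miR-29-virus cultures (2 genes, highest other split 0) and for miR-29 under OGD (4501 genes, highest other split 0), 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The 4 splits that part all 3 pairs, the real one included, gave at most 0 genes apart from the real one in both comparisons. For the averaged miR-29 effect, with 0 genes called, 100 of 100 splits gave as many, an outcome that the count of 0 fixes and that says nothing about chance. Of the other splits 4 called any gene, and the highest, 3127, set sham-empty replicate 1 and sham-miR-29 replicate 2 with the OGD-empty libraries. Of the sham libraries, these had the highest correlations with gene length (-0.0891 and 0.164). This split thus went along the gene-length trend, whose source stays open. For the interaction, 6 of 100 splits gave at least 1015 genes (highest other 2662), so that chance was not excluded. The 5 others were among 9 other splits drawn that kept the OGD libraries in their virus groups or the mirror of these. Splits that mixed the OGD libraries gave at most 0, so the share of 6 in 100 depends on how many of these were drawn. Changing the virus labels of the sham libraries alone could thus give as many genes as the real labels. The interaction splits were drawn without regard to dissection days. Their fits had no replicate block, with which the real count was 1861.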

How the results depend on the processing

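Removal of the gene-length trend, the column without read counts entered as counts, mitochondrial rows left out and genes alone in their region were chosen after seeing the data. Counts of called genes stayed within 1.5 times their value with DESeq2 size factors, without a low-count filter, with limma-voom and with mitochondrial rows left out. The strict filter removed no gene and says nothing about stability.

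The replicate block gave 1369 genes for OGD in empty-virus cultures, 5 for OGD in miR-29-virus cultures and 1861 for the interaction. It ended 6 list calls and added Mt2, Pkm and Slc1a2 for OGD in empty-virus cultures, and changed no other call of a named gene or list. Fits of the compared groups alone gave 201, 5 and, for OGD-miR-29 against sham-empty, 16. DESeq2 gave 708 for the averaged miR-29 effect. Without the length trend, counts were 379 and 18 for OGD under empty and miR-29 virus, 2853 for miR-29 under OGD, 93 for the averaged effect and 2 for OGD-miR-29 against sham-empty. With the block added, 27, 41 and 2 were called for OGD in miR-29-virus cultures, the averaged effect and OGD-miR-29 against sham-empty. Genes alone in their region, fewer by construction, gave 110 for OGD in empty-virus cultures, 561 for miR-29 under OGD, 71 for the averaged effect and 176 for the interaction. The column without read counts, entered as counts, gave 6 for OGD in miR-29-virus cultures and 489 for the averaged effect, and reversed mitochondrially encoded genes for miR-29 in sham (median 0.16, adjusted p = 0.00319) and neuron markers for OGD-miR-29 against sham-empty (0.0590, adjusted p = 0.00456). Apart from the smaller gene set, the cause was not tested.

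Leaving out libraries or replicate numbers moved counts to 0 to 984 for OGD in empty-virus cultures, 0 to 8 for OGD in miR-29-virus cultures, 2582 to 4180 for miR-29 under OGD, 0 to 1017 for the averaged effect, 0 to 1516 for the interaction and 0 to 2 for OGD-miR-29 against sham-empty. A group left with 1 library was assumed to vary like the others. The seed percentile in sham was 15.04 to 56.05 without single replicate numbers and 60.5 with the shortest UTR, for the averaged effect 48.4 with the 8-mer and 51.4 without replicate 2, and under OGD 54.3 with the 8-mer, against 77.8 and 82.4 with the 7-mer. With an estimated correlation 31 of 31 list calls were lost, and with the length trend removed 11, or 13 with the block added, each with 3 gained. Mitochondrial rows left out ended 1 (oxidative phosphorylation for miR-29 in sham). Among genes alone in their region 15 list calls were lost and 4 held, the respiratory chain for OGD in empty-virus cultures, miR-29 under OGD and the interaction, and immediate early genes for OGD in miR-29-virus cultures. Of 100 simulated 2-fold changes 3 to 55 were found, so differences of that size were often not detectable with the depth, spread and group sizes of these libraries. The simulation did not vary these apart. Fits of the compared groups alone do not apply to the averaged effect or the interaction.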

Other observations

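The test of an OGD library labelled as sham was chosen after the result was seen.

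Metallothionein transcripts, the 2 genes called for OGD in miR-29-virus cultures, separated OGD from sham libraries without overlap. They were picked from these same libraries, so the separation is not independent support. Mt2 can also hold reads of Mt1, and neither gene was called for OGD in empty-virus cultures by the main fit. Mt1 was at 14.6 to 25.9 CPM in the 5 sham libraries and at 35.7 to 85.9 CPM in the 6 OGD libraries, and Mt2 at 25.4 to 41.8 and 51.9 to 116.2 CPM. Slc1a2 was at 55.2 to 58.7 CPM in OGD-empty, at 17.8 to 30.5 CPM in OGD-miR-29 and at 24.9 to 49.96 CPM in the sham libraries.

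Sham-miR-29 replicate 2 lay toward the OGD-empty libraries in its gene-length trend (correlation 0.164, against -0.399 to -0.0891 in the other sham libraries). Mt1 in this library was at 14.6 CPM, under the lowest OGD library (35.7 CPM) and under the other sham libraries (20.8 to 25.9 CPM). That argues against an OGD library labelled as sham, without excluding it. Mt1 was picked from these same data, but was also called for OGD in miR-29-virus cultures with this library left out. Slc1a2, a long gene, was at 49.96 CPM in it. This is between the other sham libraries (24.9 to 37.8 CPM) and OGD-empty (55.2 to 58.7 CPM). Cells of another type left no sign in their marker lists, none of which was higher than in the other sham libraries. The medians were -0.0293 for microglia, -0.0848 for the oligodendrocyte lineage and -0.13 for fibroblasts and meninges on the log2 scale, over 3 to 6 members. Counts could be low (13 for Aif1 and 15 for Fcer1g in sham-miR-29 replicate 2) and shared with neighbours, so these values cannot exclude such cells. No endothelial or mural marker was measured, and no other biological explanation was tested. Across genes, the deviation of sham-miR-29 replicate 2 from its group mean correlated most with that of OGD-empty replicate 2, from the same dissection day (r = 0.232). It was 0.201 with OGD-miR-29 replicate 1, from another day. With the other same-day libraries it was -0.0898 (sham-empty replicate 2) and 0.00222 (OGD-miR-29 replicate 2). A shared day was not tested as the source.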
